A study of Homo sapiens with 6 samples.

How the data were processed

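RNA-seq was analysed from 6 libraries of C4-2B-ENZR cells, an enzalutamide-resistant human prostate cancer cell line, in 2 groups of 3. The labels describe 3 libraries from cells transfected with a negative control siRNA (NC) and 3 from cells transfected with an siRNA against KIF15 (siKIF15). Groups and replicate numbers were taken from the sample titles. No label says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

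Per the labels' protocols, total RNA was quantified by spectrophotometry, checked on a denaturing gel and made into libraries by a standard Illumina procedure. Poly(A) selection and strand were not stated there. The submitters' processing notes list Bowtie 0.12.2 and the mouse builds mm8 and mm9, although the labels give the organism as human; the human genome build and gene annotation were not given in the sources used here. The deposited files hold 1 signal value per gene symbol and library, for 17356 symbols in the same order in every file, with no header that states the unit. From the values alone, the signal appears to be gene counts that the authors adjusted to a common library size. Low values lay in bands next to whole numbers: in siKIF15 2, 252, 651, 160, 352 and 144 values lay at or within 0.5 above 1, 2, 3, 4 and 5, and none within 0.5 below. In siKIF15 3, too, none lay within 0.5 below these numbers. In NC 3 the bands lay on the other side, with 274, 648, 190 and 329 values within 0.5 below 1, 2, 3 and 4 and none above. In NC 1, NC 2 and siKIF15 1 the bands were less sharp: in NC 1, 215 values lay at or within 0.5 above 3 and 110 below it, and in NC 2, 139 lay at or above 5 and 167 below it. A floor far below 1 was shared by 518 genes in each NC library and by 622 in each siKIF15 library. This reading is an inference, and reads were not recovered from the values. The depth of each library is therefore unknown. The sums of the values are not depths, and no counting interval or count model was used in the tests of these values.

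The plan made before the data were examined named tests for counts and for FPKM-type values. The test planned for normalized values was applied to the signal: limma with an intensity-dependent variance trend on log2(value + 1), over the 16548 genes with a mean of at least 1 in at least 1 group. All 6 libraries entered 1 fit with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are siKIF15 minus NC on the log2(value + 1) scale, which understates the change of low genes. Some genes that cells generally use lie at or near the floor in a whole group, so such a value is not read as absence. Examples are the proteasome subunit PSMA7 in NC and the mitotic genes AURKA, UBE2C and TPX2 in both groups. The lists that hold such genes were tested with these values included. Library values are rounded to 1 decimal, so a printed 0 can be a smaller value above 0. Genes with near-identical copies (IFNL2 and IFNL3, HLA, KRT6, KRT16 and KRT17, C4, and histone genes) are uncertain, since how reads shared between copies were counted is not stated. Overlapping and antisense genes are uncertain for the same reason.

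At the same time 26 gene lists were fixed. They covered mitosis, DNA replication, p53 targets, interferon response, ATF4 stress, endoplasmic reticulum chaperones, cholesterol synthesis and hypoxia with glycolysis. They also covered neuroendocrine, luminal epithelial and mesenchymal genes, immediate early genes, nucleolar ribosome biogenesis, the proteasome, tubulins with motors, kinesins, ribosomal proteins, oxidative phosphorylation and histones. Markers of basal epithelial, fibroblast, immune and endothelial cells stood for other cell types, and genes encoded by mitochondrial DNA made up the last list, which was not analysed here. The 25 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. A further 10 lists were written after the largest changes had been seen, and 9 of these were tested in the same way as a separate family. Of the symbols, 16436 were found in RefSeq and 590 older symbols were matched through its synonyms. A further 25 lines carried symbols turned into calendar dates (23 distinct, 2 of them on more than 1 line); these stayed in the tests and are not named.

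The text names KIF15 and KLK3 whatever their values, and the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 in the higher group and no overlap between the groups. For each list past its own test, up to 4 members with the smallest adjusted p were eligible. Any other named gene was chosen after its values were seen: the members of a count of 5 or fewer, the members of the lists written later, IL2RG, the mitotic genes near the floor and the abundant genes that fell. Some genes that this rule takes, and 2 of the fixed lists, are not reported here.

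GC content and length were taken from the longest transcript of each gene in GENCODE 29 and were found for 16112 of the genes tested; gene positions are on GRCh38 and may not match the authors' annotation. A correction subtracted, per library, a smooth trend (splines with 4 degrees of freedom) on both properties, fitted on genes with a mean log2 value above that of 100. Replicates were compared over 11384 genes with a mean of at least 100: the squared difference divided by the sum averaged 6.11 to 63.6 per gene between libraries of 1 group and 85.1 to 162 between groups, and no library repeated another. Other settings chosen before the data were examined covered the replicate number as a block, each library left out, filters, scaling, variance settings, library weights, pseudocounts, thresholds and list tests. The GC and length correction, a pseudocount of 8 and a restriction to genes with a mean of at least 100 were added after seeing the data.

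The fit was tested on simulated values for the comparison of siKIF15 with NC, over 16449 genes. It called 38 of 50 genes changed 1.3-fold, 44 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 50 of 50 changed 4-fold in the right direction, with 4 unchanged genes called. Of 100 random lists, 3 had p under 0.05. Changed genes and random lists came from genes with a mean of at least 50. Values were drawn as whole numbers from a negative binomial count model, with the median dispersion of genes of similar mean. The deposited values are not whole numbers. Genes were drawn independently, without the correlation between genes or the GC and length trends of the real libraries. The simulation therefore does not show how often the fit or the list tests call falsely in the real data. Analyses used R 4.3.3, limma 3.58.1 and Python 3.11.15.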

Results

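The transcriptome of C4-2B-ENZR cells, a prostate cancer line that grows in the presence of the prostate cancer drug enzalutamide, was measured by RNA-seq after transfection with a negative control siRNA (NC, n = 3) or an siRNA against KIF15 (siKIF15, n = 3). The study's title links KIF15, a kinesin motor of the mitotic spindle, to enzalutamide resistance, and the comparison asks which transcripts differ after its knockdown. Values are the deposited signal per gene, whose sequencing depth is unknown. The first principal component held 46.7% of the variance and separated the 2 groups. The second held 14.8% and separated siKIF15 2 from siKIF15 3, with scores of 36.2 and -48.

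The targeted transcript was not lower by the test. KIF15 (chromosome 3, 44761717 to 44873376, GRCh38) stood at 366.4, 403.6 and 319 in the NC libraries and at 294.8, 333.1 and 363 in the libraries labelled KIF15 knockdown. Its log2 change was -0.13 ± 0.14 (SE; 95% interval -0.43 to 0.16; limma adjusted p = 0.57), within the spread between libraries. Because the targeted gene does not bear out the label, every direction below is that of the libraries labelled KIF15 knockdown against the NC libraries. KLK3, the gene for prostate-specific antigen, averaged 64846 ± 2407.4 (SD, n = 3) in NC and 68868.6 ± 4123.8 in siKIF15, a log2 change of 0.09 (adjusted p = 0.49).

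Interferon and interferon-stimulated genes gave the largest rises. IFNB1 (chromosome 9, 21077105 to 21077963), which encodes interferon beta, was listed at 1.7, 0.1 and 1.9 in NC and at 2240.7, 2388.1 and 2119.2 in the libraries labelled KIF15 knockdown (log2 change 10.1 ± 0.33 SE, adjusted p = 2.9e-12). IFNL1, a type III interferon, was listed at 0, 2.4 and 0.9 in NC and averaged 2186.9 ± 146.2 in siKIF15. IFNL3 was at the floor of the values, far below 1, in every NC library and at 449.3, 490.6 and 391.2 in siKIF15, so no fold is given. OASL rose from 285.6 ± 30.6 to 80171.2 ± 4599.9, a 280-fold change, and IFIT2, which binds viral RNA, rose 231-fold from 233.2 ± 24.3 to 54012.7 ± 4861.3. The ubiquitin-like modifier ISG15 averaged 6907.9 ± 167.6 in NC and 159452.7 ± 19859 in siKIF15, a 23-fold rise. The chemokine genes CXCL10 and CXCL11 rose from means of 3.7 and 1.7 to means of 2071.8 and 643.7. Also among the 10 largest rises were the keratin gene KRT16 (3.7 ± 3 to 2042.9 ± 219.7) and OAS2 (11.4 ± 5.1 to 2805.4 ± 236.8).

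Of the 32 measured interferon-response genes, 30 rose and none fell, and 31 rose when adjusted over the list alone. The list median was a log2 change of 3.07, and the per-library medians were 3.12, 3.09 and 2.93 in siKIF15. The list passed its test against all other genes (camera adjusted p = 8.9e-63), and was the only 1 of the 25 lists to do so with an estimated correlation (adjusted p = 0.002). IFIT1 (log2 change 7.52 ± 0.08 SE) was among its members with the smallest adjusted p. The members that did not pass were STAT2, at a log2 change of 0.26 (adjusted p = 0.051), and IFI44L, at the floor in every NC library and at 1.8, 2.1 and 2.1 in siKIF15 (adjusted p = 0.19).

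**Figure D1:**
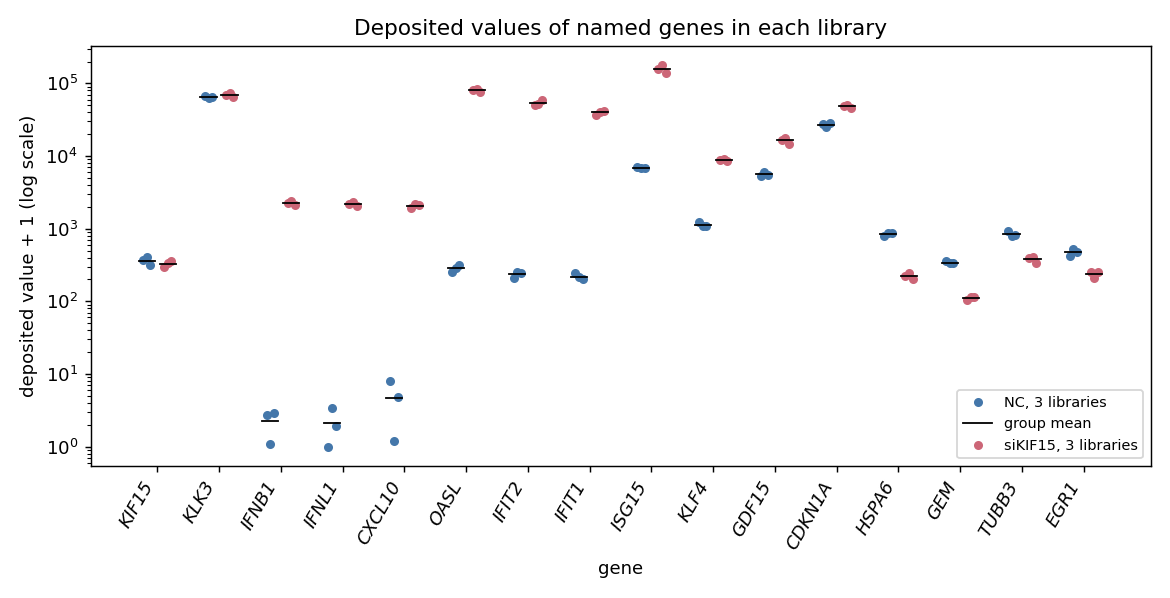
Deposited values plus 1 (vertical log axis) of 16 genes (horizontal axis) in each of the 6 libraries; points are libraries, blue for NC and red for siKIF15, and black lines are means of the 3 libraries. KIF15 and KLK3 overlap between the groups, IFNB1 lies below 3 in NC before the 1 is added and above 2119 in siKIF15, and HSPA6 averages 849.7 in NC and 223.9 in siKIF15.

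Across the transcriptome, 2978 of 16548 genes passed an adjusted p of 0.05, with 1599 higher and 1379 lower in the libraries labelled KIF15 knockdown. Large changes were mostly rises: 465 genes rose and 76 fell by a log2 change of at least 1, and among genes with a mean of at least 100 these counts were 176 and 12. Most calls were small, since 1733 had an absolute log2 change under 0.5. The groups did not overlap for 5758 tested genes (34.8%, where chance gives 10%), and for 2931 of those called. The count of calls was 1802, 1366 and 1723 without NC 1, NC 2 or NC 3, and 1184, 2187 and 5077 without siKIF15 1, siKIF15 2 or siKIF15 3. The same libraries scaled to equal totals gave 1205 higher and 1753 lower, so the balance of rises and falls depends on the scaling. Of 74 genes chosen after their values were seen, some of them not called, 30, 27 and 30 lost their call without NC 1, NC 2 or NC 3, and 34, 21 and 1 without siKIF15 1, siKIF15 2 or siKIF15 3. Fewer libraries also lower the power of the test, and the cause of these losses was not tested.

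Several p53 targets rose. GDF15, a stress-induced secreted factor, rose from 5591 ± 331.4 to 16460.7 ± 1538 (SD, n = 3; 2.94-fold), the antiproliferative gene BTG2 rose 2.2-fold, and CDKN1A, which encodes the cell cycle inhibitor p21, rose 1.79-fold from 27093.8 ± 1735.3 to 48508.7 ± 2455.5. XPC, a DNA repair gene, rose 1.47-fold. In all, 7 of 24 measured p53 targets rose and 3 fell, namely TP53INP1, ZMAT3 and SESN2, and 11 rose and 3 fell when adjusted over the list alone. The list median was 0.12 (camera adjusted p = 0.014; adjusted p = 0.17 with an estimated correlation), and the call ended without siKIF15 3 (adjusted p = 0.059).

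DNA replication genes rose by small amounts: 11 of 35 measured rose, none fell, and 14 rose when adjusted over the list alone. GINS2 and CDC45, parts of the replicative helicase, both rose 1.43-fold, and MCM2 rose 1.27-fold from 8343 ± 222.7 to 10558.8 ± 312.8. The median was 0.18 (camera adjusted p = 3.5e-05; adjusted p = 0.17 with an estimated correlation). Mitotic genes did not pass as a list (median -0.04, adjusted p = 0.32; medians from -0.09 without siKIF15 3 to -0.02 without siKIF15 2): of 41 measured none rose and 4 fell, namely CENPF, ASPM, ECT2 and ANLN, and none passed when adjusted over the list alone. CENPF fell by 0.48, from 1655.5 ± 29.8 to 1212.2 ± 289.8. The calls of these 4 genes ended without NC 1, NC 2, NC 3, siKIF15 1 or siKIF15 2 (adjusted p of CENPF 0.064, 0.12, 0.06, 0.14 and 0.058).

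Luminal epithelial genes rose, with 9 of 20 measured higher and 1 lower, and 12 higher and 1 lower when adjusted over the list alone. The tight junction genes CLDN4 and CLDN7 rose 1.77-fold and 1.44-fold, CLDN4 from 33446.3 ± 578.6 to 59257.9 ± 5831. TJP1, a tight junction scaffold gene, fell 1.51-fold. The median was 0.24 (camera adjusted p = 0.00049; adjusted p = 0.16 with an estimated correlation). Basal epithelial markers also rose: of 10 measured, 5 were higher and 1, DST, was lower, and 7 rose and 1 fell when adjusted over the list alone. COL17A1, a hemidesmosome collagen, rose 18.9-fold from 11.7 ± 4.1 to 229.7 ± 15.3. KRT17 was at the floor in every NC library and at 39.6, 37.5 and 23.8 in siKIF15, whereas KRT5 was at the floor in NC and at 2.7, 5.2 and 1.1 in siKIF15 (adjusted p = 0.13). The basal median was 1.44 (camera adjusted p = 0.00098; adjusted p = 0.17 with an estimated correlation).

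Among markers of other cell types, 3 of 9 measured leukocyte genes rose and none fell, both over all genes and adjusted over the list alone. HLA-DRA, an MHC class II chain, averaged 1.8 ± 1.7 in NC and 233.4 ± 37.3 in siKIF15, and CD74, its invariant chain, 2.2 ± 3.1 and 176.1 ± 7.8. CD68, a lysosomal protein gene, rose 1.83-fold from 1783.3 ± 133.2. PTPRC, the common leukocyte antigen, was at the floor in the 3 siKIF15 libraries. The list median was 0.62 (camera adjusted p = 0.04; adjusted p = 0.25 with an estimated correlation), and the call ended without siKIF15 1 or siKIF15 3 (adjusted p = 0.11 and 0.08). Its median was 0.13, 0.23, 0.33 and 0.10 without NC 1, NC 3, siKIF15 1 or siKIF15 2. Of 10 measured fibroblast markers, FAP and PDGFRA rose, to means of 6.6 and 5.9, and none fell, with 2 rises adjusted over the list alone. These values lie near the floor, and the calls of FAP and PDGFRA ended in 7 and 10 of their 19 alternatives. The fibroblast list had a median of -0.11, a mean of 0.33 and an adjusted p of 0.73. The median ranged from -0.27 without NC 1 to 1.04 without NC 2, was 0.16 without siKIF15 3, and the list did not pass in any of these fits. None of 6 measured endothelial markers passed, also adjusted over the list alone (list adjusted p = 0.3).

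Immediate early genes moved in both directions. KLF4 rose 7.74-fold from 1140 ± 78.6 to 8822.2 ± 189.2, ZFP36 rose 1.67-fold and CYR61 1.8-fold, while EGR1 fell by 0.99 on the log2 scale from 472.8 ± 56.8 to 236.5 ± 22.9. Of 20 measured, 7 rose and 4 fell (EGR1, FOSB, FOS and MYC), and 8 rose and 4 fell when adjusted over the list alone. The list median was 0.1 (camera adjusted p = 0.048; adjusted p = 0.58 with an estimated correlation). Among chaperones and unfolded protein response genes of the endoplasmic reticulum, 8 of 20 rose and 2 fell (EDEM1 and SEL1L), the same counts as adjusted over the list alone. XBP1, a transcription factor gene of that response, rose 1.75-fold from 16897.7 ± 144.3 to 29664.8 ± 1330.2. The list median was 0.13 (camera adjusted p = 0.048; adjusted p = 0.54 with an estimated correlation). The immediate early call ended without NC 2, NC 3, siKIF15 1 or siKIF15 2 (adjusted p = 0.089, 0.057, 0.13 and 0.068), and its median was 0.19 without NC 1 and without siKIF15 3. The chaperone call ended without NC 1, NC 3, siKIF15 2 or siKIF15 3 (adjusted p = 0.093, 0.12, 0.057 and 0.085). In all, the chaperone call was lost in 17 of its 22 alternatives and the immediate early call in 12 of 22.

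**Figure D2:**
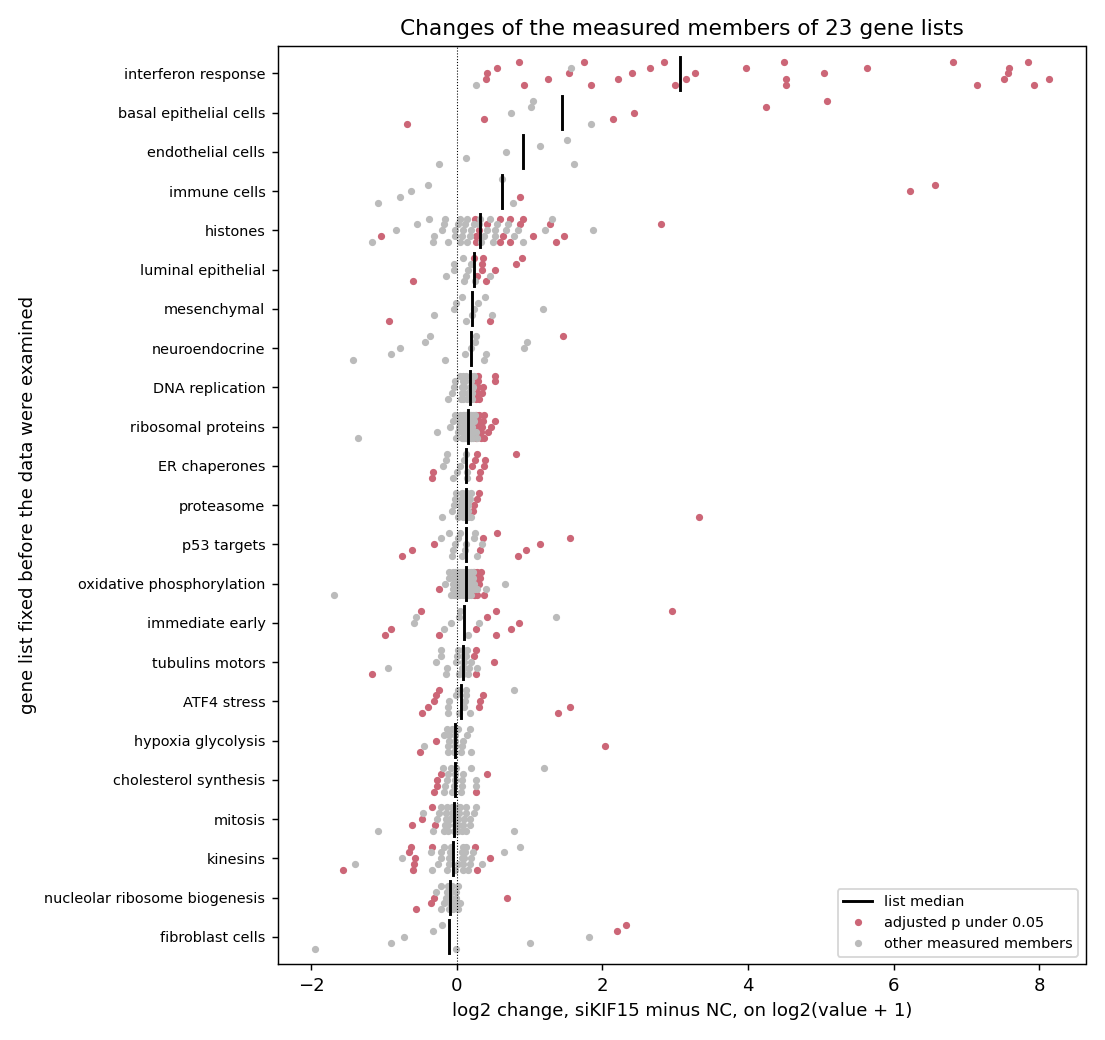
Log2 change, siKIF15 minus NC, on log2(value + 1) (horizontal axis) of every measured member of 23 lists (rows, sorted by median); red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The interferon response has the highest median, 3.07, and the ribosomal protein and oxidative phosphorylation medians are 0.16 and 0.12.

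Lists of ribosomal protein, oxidative phosphorylation, histone and proteasome genes rose slightly. Of 79 measured ribosomal protein genes 19 rose and none fell, and 26 rose when adjusted over the list alone. The median was 0.16 (camera adjusted p = 2e-07; adjusted p = 0.58 with an estimated correlation). Its median was 0.17, 0.28 and 0.04 in siKIF15 1, 2 and 3. RPS27L rose 1.38-fold and RPS27 1.44-fold. Of 78 oxidative phosphorylation genes 12 rose and 1, NDUFS1, fell, and 12 rose and 1 fell when adjusted over the list alone. The median was 0.12 (camera adjusted p = 0.0011; adjusted p = 0.58 with an estimated correlation). COX7B and COX7A2, small subunits of cytochrome c oxidase, rose 1.3-fold and 1.21-fold. This list's medians in siKIF15 1, 2 and 3 were 0.13, 0.21 and 0. Of 59 histone genes 17 rose and 1, HIST1H4I, fell, and 18 rose and 3 fell when adjusted over the list alone. The histone median was 0.32 (camera adjusted p = 0.00092; adjusted p = 0.17 with an estimated correlation). HIST1H2BD rose 1.83-fold from 1432.1 ± 58.2 to 2621.2 ± 117.2. The histone medians in siKIF15 1, 2 and 3 were 0.32, 0.4 and 0.29. Of 31 proteasome genes 5 rose (PSMA7, PSMC3, PSMA6, PSMA5 and PSMC1) and none fell, with 4 rises adjusted over the list alone. The proteasome median was 0.12 (camera adjusted p = 0.0048; adjusted p = 0.58 with an estimated correlation). PSMA7 was at the floor in NC and at 3.3, 19.7 and 10.3 in siKIF15. PSMC3 rose 1.24-fold. The proteasome medians in siKIF15 1, 2 and 3 were 0.09, 0.23 and 0.04. After correction for GC content and transcript length, chosen after seeing the data, the medians of these lists were 0, -0.05, 0.06 and -0.02 and none passed. Without siKIF15 2, the oxidative phosphorylation and proteasome calls ended (adjusted p = 0.08 and 0.063), and the ribosomal protein, oxidative phosphorylation and proteasome medians were 0.10, 0.07 and 0.05.

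The libraries differed in GC content and transcript length. Over 11231 genes, which are not independent replicates, the Spearman correlation of a library's deviation from its group mean with GC content was 0.55, 0.52 and -0.75 in siKIF15 1, 2 and 3. With transcript length it was 0.04, -0.65 and 0.54. In the NC libraries these correlations were 0.17, -0.31 and 0.2 for GC content and -0.24, 0.07 and 0.16 for length. These values describe the spread within a group. The change of siKIF15 1, 2 and 3 from the NC mean had correlations of 0.51, 0.47 and -0.1 with GC content and of -0.34, -0.54 and -0.09 with length. After the correction 4561 genes were called, of which 2549 were also called before in the same direction, and 1953 were higher and 2608 lower. The interferon-response median was then 2.89, and the basal, luminal, DNA replication, p53 and nucleolar medians were 1.36, 0.22, 0.12, 0.1 and -0.17, with their camera calls kept. With an estimated correlation the corrected interferon list passed (adjusted p = 0.0039) and these 5 did not (adjusted p = 0.16, 0.11, 0.26, 0.24 and 0.3). The calls of the leukocyte, chaperone and immediate early lists ended (adjusted p = 0.068, 0.26 and 0.14), with medians of 0.62, 0.13 and 0.1 before and 0.57, 0.06 and 0.07 after, so the leukocyte call ended with little change of its median.

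**Figure D3:**
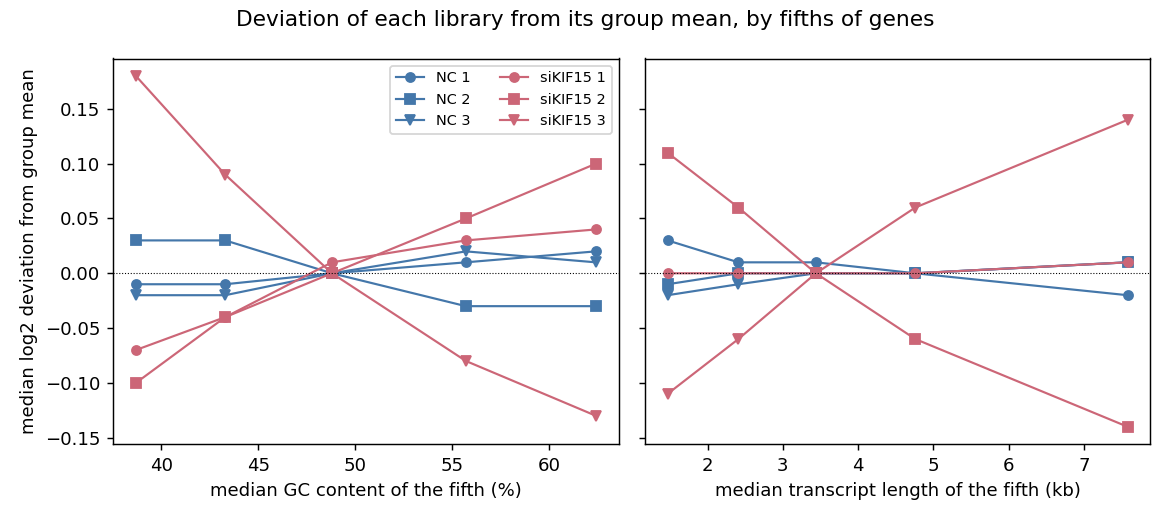
Median log2 deviation of each library from its group mean (vertical axis) over 5 groups of nearly equal size, made from 11231 genes ordered by GC content in percent (left) and transcript length in kb (right); blue lines are NC libraries and red lines siKIF15 libraries, with marker shapes for replicates. In the group with the lowest GC content the medians are -0.1 in siKIF15 2 and 0.18 in siKIF15 3.

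The 10 largest falls lay near the floor of the values. FGF18, a fibroblast growth factor gene, stood at 45.5, 37.5 and 38.8 in NC and at 0, 17.5 and 0 in siKIF15. BNC2 and SMIM18 averaged 13.9 ± 3.5 and 9.6 ± 3.5 in NC and were at the floor in every siKIF15 library. CUBN, PIK3CG and PKD1L3 averaged 17.5, 25 and 16.9 in NC and 0.7, 2.4 and 1.7 in siKIF15. CLEC2B, GPR142, MAP7D2 and NTNG2 averaged 45.5, 22.5, 14.2 and 28.3 in NC and 7.5, 2.3, 2.7 and 3.3 in siKIF15. The calls of FGF18 and CLEC2B ended without NC 2 (adjusted p = 0.053 and 0.08) or siKIF15 1 (adjusted p = 0.085 and 0.055). That of MAP7D2 ended without NC 1, NC 2, NC 3 or siKIF15 1.

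Nucleolar ribosome biogenesis genes were lower as a list (median -0.09, camera adjusted p = 0.031; adjusted p = 0.33 with an estimated correlation), although NOLC1, its member with the smallest adjusted p, rose 1.62-fold. Of 23 measured, 3 fell (UTP20, WDR43 and PPAN) and 1 rose, the same counts as adjusted over the list alone, and the call ended without siKIF15 1 or siKIF15 3 (adjusted p = 0.058 and 0.072). After the GC and length correction 16 members were lower and 1 higher, with a median of -0.17. Kinesin genes other than KIF15 did not pass as a list (median -0.05, adjusted p = 0.21; medians of 0.03, 0.02 and -0.13 without NC 1, siKIF15 1 or siKIF15 3), with 3 of 40 higher (KIF9, KIF1C and KIF22) and 7 lower, the same counts as adjusted over the list alone. Of 28 tubulin and motor genes 4 rose (TUBB6, DCTN2, TUBA1C and TUBG1) and 1, TUBB3, fell, with 4 rises and 3 falls adjusted over the list alone (list adjusted p = 0.4). Of 22 ATF4 stress genes 5 rose (NUPR1, PPP1R15A, ATF4, DDIT4 and JDP2) and 5 fell (SLC7A11, SESN2, DDIT3, VLDLR and SLC7A5), with 6 rises and 5 falls adjusted over the list alone (list adjusted p = 0.41). PPP1R15A, a regulator of eIF2 alpha dephosphorylation, rose by 1.55 ± 0.11 (SE).

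Of 25 cholesterol synthesis genes 2 rose, among them FDPS, and 4 fell (SCD, FASN, ACACA and MSMO1), with 3 rises and 4 falls adjusted over the list alone; the median was -0.03 (-0.06 to -0.01 without single libraries), the mean 0.03 and the adjusted p 0.68. Of 22 hypoxia and glycolysis genes ADM rose and HK2 and PDK1 fell, the same counts as adjusted over the list alone; the median was -0.03 (-0.07 to -0.01 without single libraries), the mean 0.03 and the adjusted p 0.48. Of 15 neuroendocrine genes only SCN3A passed, rising from 19.4 ± 2.3 to 55.2 ± 3.8, as it did adjusted over the list alone (list adjusted p = 0.87). Of 13 mesenchymal genes FN1, the fibronectin gene, rose and SNAI1 fell, the same counts as adjusted over the list alone (list adjusted p = 0.51).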

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

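The GC and length correction, the pseudocount of 8 and the restriction to genes with a mean of at least 100 were chosen after seeing the data; the other alternatives were chosen beforehand. KIF15 kept its direction and did not pass in any of its 20 alternatives (log2 change -0.24 to -0.04, adjusted p 0.053 to 0.87), the lowest p coming from library quality weights, whose estimation stopped before it converged. The interferon-response list passed in all 22 of its alternatives. The count of genes past the threshold was 2978; it was 1070 without the variance trend, 7502 with quality weights, 4561 with the GC and length correction, 541 with an absolute log2 change of at least 1, 1541 at an adjusted p under 0.01, and 1184 to 5077 when single libraries were left out. The stricter thresholds lower the count by construction; for the others the cause was not tested. Scaling to the same total gave 1205 higher and 1753 lower, against 1599 and 1379, with the median of all genes moved by -0.06. The count of lists past the threshold was 13; it was 6 with the GC and length correction and 1 with an estimated correlation, and 9 to 12 without single libraries. With that correction KLK3 was at -0.09, PDK1 at 0.04, NDUFS1 at 0.01, the oxidative phosphorylation median at -0.05 and the ATF4 stress median at -0.04, each with the opposite sign. The neuroendocrine list was turned to lower with no filter (median -0.03) and without NC 3 (median 0.04, though its test was negative), with medians from -0.06 to 0.26 over the libraries left out; TP63 was at -0.16 with quality weights. None of these reversed values passed, and the cause was not tested. Of the 69 genes named by rule other than KIF15, 23 lost their call without the variance trend, 15 without NC 2 and 18 without siKIF15 1, and 0 with the replicate block. With the replicate number as a block, KIF15 was at -0.13, 3184 genes and 11 lists passed, and the chaperone and nucleolar lists lost their call. Same-numbered libraries deviated from their group means with correlations of 0.02, -0.02 and 0.02. Only the libraries numbered 3 correlated best with their own number. The values thus show no pairing by number, but no label says whether same-numbered libraries were prepared together. Depth is unknown, so the precision of low values cannot be stated from counts.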

Other observations

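The tests in this part, and the 10 further gene lists, were chosen after the results were seen. The lists hold genes already seen to rise, such as CXCL10, CXCL11, KRT16, HLA-DRA and CD74. Their p-values therefore describe the lists and are not separate support. The lists also share members: HLA-DRA and CD74 are in the leukocyte and MHC class II lists, and KRT5, KRT14, KRT15 and KRT17 in the basal and keratin lists. CXCL8 is in the chemokine and NF-kappa B lists. Genes of antigen presentation were higher in the libraries labelled KIF15 knockdown. Of 17 measured MHC class I genes 14 rose and none fell (median log2 change 0.8, camera adjusted p = 1.7e-15; adjusted p = 0.034 with an estimated correlation); B2M rose by 1.61 ± 0.07 (SE) from 24463.7 ± 678.3 (SD, n = 3) to 74572.9 ± 3809.5, HLA-B by 1.28 and the immunoproteasome gene PSMB9 by 1.83. Of 11 MHC class II genes 9 rose and none fell (median 2.25; adjusted p = 0.025 with an estimated correlation), among them HLA-DRB1, at the floor in every NC library and at 37.7, 38.6 and 24.9 in siKIF15. Of 15 chemokine genes 9 rose and none fell (median 2.31; adjusted p = 0.024 with an estimated correlation), CCL5 from 13.7 ± 4.3 to 2771.4 ± 307.9. Genes of viral RNA sensing rose in 4 of 7 (median 0.71; adjusted p = 0.025 with an estimated correlation), among them DDX58, which encodes RIG-I, by 4.5 ± 0.11 and IFIH1 by 2.84 ± 0.12. EIF2AK2, TICAM1 and TRIM25 did not pass. DDX58 and IFIH1 also belong to the interferon-response list, so this test is not separate from that one.

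Of 16 measured NF-kappa B targets 9 rose and 1 fell (median 0.41; adjusted p = 0.038 with an estimated correlation), with BIRC3 at 2.73, IRF1 at 1.19 and TNF at 1.97. Complement genes rose in 3 of 12 (median 0.4; adjusted p = 0.038 with an estimated correlation), with a median of 0.67, 0.24 and 0.25 without NC 1, NC 3 or siKIF15 3. CFB rose from 32.8 ± 13 to 2368.2 ± 44.6 and C3 from 3.4 ± 3 to 384.3 ± 49.1. Of 14 genes of death ligands, caspases and pyroptosis 5 rose and none fell (median 0.29, camera adjusted p = 0.0018; adjusted p = 0.094 with an estimated correlation), with a median of 0.15 and 0.18 without NC 1 or siKIF15 3. The death ligand gene TNFSF10 rose by 2.74. The cytokine receptor gene IL2RG rose from 7.8 ± 8.4 to 208.2 ± 49.3. The heat shock list did not pass (median -0.08, camera adjusted p = 0.052; adjusted p = 0.22 with an estimated correlation), although it passed as lower after the GC and length correction (median -0.11, adjusted p = 0.0031) and without NC 1, NC 3, siKIF15 2 or siKIF15 3 (adjusted p = 0.047, 0.033, 0.025 and 0.035), among other settings. Its member HSPA6 fell by 1.92 ± 0.12, from 849.7 ± 39.8 to 223.9 ± 21.1. It is 1 of 12 genes with a mean of at least 100 that fell by a log2 change of 1 or more. Others among them were GEM, a GTPase gene (338.2 ± 12.8 to 110 ± 6.4), VWA2 (179.1 to 63.8), PGR, the progesterone receptor gene (302.9 to 124.4), TUBB3, a neuronal beta tubulin gene (845.3 to 378.5), BHLHE41 (430 to 200.3) and IRS2 (223.6 to 104.4).

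The interferon response in libraries whose KIF15 transcript did not pass as lower is the pattern most in need of follow-up. After the GC and length correction its list median was 2.89. The correction removes only the fitted trend, so this value alone does not decide whether GC content and length were the cause. Median log2 changes of genes grouped by GC content ran from -0.16 to 0.08, and by transcript length from -0.18 to 0.11. Only genes with a mean log2 value above that of 100 were grouped. Trends of that size in such genes fall far short of the interferon list median of 3.07 before correction. List members below that limit are not covered. Leukocytes as carriers of these transcripts are argued against by the 9 measured leukocyte markers, whose summed values (1846.1 ± 125.2 in NC and 3732.8 ± 343.1 in siKIF15, mostly CD68) rose by 0.44% of the rise of the interferon list, which went from 32599 to 459981; a few leukocytes that release interferon are not excluded. A KIF15 transcript at a log2 change of -1 or below at harvest is argued against by the lower limit of its interval, -0.43. An earlier or protein-level loss was not tested. All 4 of IFNB1, IFNL1, IFNL2 and IFNL3 rose as transcripts. These rises are part of the pattern and were known before the check was set, so they do not decide whether interferon acted on the cells. Interferon protein was not measured. Whether the siRNA duplex itself, loss of KIF15 protein or another difference between the labelled groups lay behind the interferon response stays open, as the design has 1 comparison.

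A candidate explanation for the small rises of ribosomal protein and oxidative phosphorylation genes is the difference in GC content and transcript length between libraries, which against the NC mean was near 0 in siKIF15 3 (correlations of -0.1 and -0.09) and larger in siKIF15 1 and 2. After correction the ribosomal protein median went from 0.16 (interquartile range 0.14) to 0.00 (0.17), and the oxidative phosphorylation median from 0.12 (0.2) to -0.05 (0.19), and both calls ended because the medians moved to about 0. The correction also removes any real change that follows length, which stays open.

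Several keratin and basal genes rose, while KRT5 and KRT15, keratins of basal epithelial cells, averaged 3 and 1.3 in siKIF15. Of 10 measured basal markers 5 were higher and 1 was lower, and that list did not pass with an estimated correlation (camera adjusted p = 0.17). Of 25 measured keratin genes other than KRT8, KRT18 and KRT19, 10 rose and none fell (median 0.51; adjusted p = 0.038 with an estimated correlation; 0.37 after the GC and length correction), with KRT6C from 15.9 ± 9.6 to 493.3 ± 50.1, KRT6B from 3.5 ± 4.5 to 140.1 ± 18 and KRT36 from 1.9 to 97.2. The basal list median was 1.44 before the GC and length correction and 1.36 after it. Here too the correction removes only the fitted trend, so the corrected value alone does not decide. Median log2 changes of genes grouped by GC content or length lay between -0.18 and 0.11. Only genes with a mean log2 value above that of 100 were grouped. KRT5, KRT14, KRT15, KRT17, COL17A1 and NGFR lay below that limit, so these trends do not bound their changes. KRT5, KRT14, KRT15 and KRT17 summed to 4.09% ± 0.905 (SD, n = 3) of KRT16 in siKIF15 (KRT14 46.1 and KRT17 33.7, against 2042.9). KRT5 and KRT15 lie near the floor, which is not read as absence. The counting of reads shared between KRT14, KRT16 and KRT17 is not stated. The share therefore does not decide whether basal or squamous cells carried KRT16. For the smaller rises of KRT14, KRT17, COL17A1 and NGFR such cells stay open too, since KRT5 at 6.51% of KRT14 lies near the floor and does not decide. A change of keratin expression in the cancer cells themselves was not tested.

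The real grouping called 2978 genes, and the highest count among the other splits of the 6 libraries into 3 and 3 was 1. These 10 splits are too few for a share under 0.05. Every other split also mixed libraries of both groups, so the difference between the groups widened the spread within each side. Low counts were therefore likely from the start and do not tell how many genes would pass without a group difference.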
